A study of Arabidopsis thaliana with 6 samples.

How the data were processed

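Mitochondria were isolated from the youngest leaves of wild-type plants and of the P2 and P3 phenotypes of a heterozygous rps10 mutant, and each footprint and RNA library was made from 15 pooled preparations, per the labels' protocols. About 30 g of leaves went into each wild-type isolation and about 15 g into each mutant isolation. Chloramphenicol, which holds mitochondrial ribosomes in place, was added to 100 µg/ml on thawing, unprotected RNA was digested with nuclease, ribosomes were collected through a sucrose cushion and rRNA was depleted with a Ribo-Zero kit, per the labels' protocols. Plants grew in 8 h of light and 16 h of dark, and only mutant seedlings were raised on kanamycin. Samples were grouped by the library titles in the labels into 6 groups of 1 library.

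The submitters' processing notes name STAR and featureCounts. Their versions and settings, the genome build and the annotation are not given in the sources used here. Gene levels were deposited as TPM over 24 mitochondrial genes, per the file headers, and each library's TPM summed to 1000000 over those genes. A gene's TPM is therefore its part of those 24 genes and not an amount per mitochondrion or per leaf. A summary sheet per library held whole numbers of reads in each class of sequence, and the deposited fraction beside each number was relative to reads after trimming and filtering in its first block and to reads on the mitochondrial genome in its second. Codon periodicity was deposited as a fraction of footprints in each frame per gene, exon or open reading frame. How the authors assigned footprints to frames and which read lengths they kept is not given in the sources used here.

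Log2 ratios of TPM were computed per gene for P2 over wild type, P3 over wild type and P3 over P2, without a pseudocount, since no value was 0. Translation efficiency was the footprint TPM divided by the RNA TPM of the same kind of plant. Genes at least 1.5-fold apart (0.58 on the log2 scale) were counted in each direction. With 1 library per group no test was possible. An interval per gene from read counts had been planned and was not computed because gene levels were in TPM, and an interaction model of footprint and RNA counts was left out because it would have no residual degrees of freedom. Shares of reads carry 95% Wilson intervals, which cover counting error only. Over libraries of 48653 to 3126478 reads on CDS such intervals are narrow, and the variation between plants and preparations, which they leave out, is unknown.

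Lists of genes were fixed before the data were examined: complexes I, III, IV and V, these together as OXPHOS, cytochrome c maturation, small-subunit and large-subunit ribosomal proteins and both together, a pair of other genes (matR and tatC), intron-containing genes, trans-spliced genes and plastid and nuclear genes as markers of other compartments. Of the members, 4 of 9 complex I genes, 1 of 1 complex III gene, 2 of 3 complex IV genes, 6 of 6 complex V genes, 4 of 5 cytochrome c maturation genes and 5 of 7 ribosomal genes had TPM. The intron-containing, trans-spliced and other-compartment lists had 0 members with TPM, so intron-containing genes entered through their exons in the periodicity data and other compartments through classes of reads. A list's median was placed among 10000 random lists of the same size drawn with the same number of genes from each tertile of mean TPM. That mean was taken over the libraries compared, mutant and wild type, so a gene's own change can move its tertile. The genes named in the text are RPS10 where listed, those past 1.5-fold in the same direction in both phenotypes, the 5 highest and 5 lowest ratios of each comparison, and members of the fixed lists given with their value. All 24 gene names matched the TAIR10.1 gene table, 3 of them through another name of the gene, and that table was used only for names and neighbouring genes.

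The P2 and P3 ratios were compared by Pearson r, Spearman rho and covariance over genes, beside 10000 simulated sets of unchanged libraries that shared the wild-type library. Poisson draws had been planned for this. Without read counts per gene, normal noise on the log2 scale was drawn instead, set per library from the spread of P3 over P2. Any true difference between P2 and P3 therefore counts as noise, and a deviation of the wild-type library beyond that spread is not covered. The overlap of independent lists was the product of both list sizes over 24. The arithmetic was tested on simulated data with noise of 0.05 (SD on the log2 scale), where 12 of 12 genes changed 3-fold were recovered in footprints and in efficiency. That noise is somewhat below the value derived from these libraries for RNA (0.069) and far below that for footprints (0.29). The 1.5-fold rule was then run on 1000 simulated sets with these derived values as the noise of each library (0.29 for footprints and 0.069 for RNA). For footprints of P2 over wild type it recovered 11.3 of 12 genes changed 3-fold on average but also called 4.61 of 12 unchanged genes, or 1.83 once ratios were centred on the median gene. For efficiency of P2 over wild type it recovered 11.2 and called 4.61 unchanged genes, or 1.91 once centred. In P3, without centring, the rule called 4.58 unchanged genes for footprints and 4.66 for efficiency. Without centring, all changed genes and no unchanged gene were called in 28 of the 1000 sets for footprints of P2 and in 26 for efficiency.

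Alternatives fixed before the data were examined were median-of-ratios scaling, leaving out the most abundant gene, a 2-fold threshold, pseudocounts of 100 and 1 TPM, a minimum mean of 1000 TPM, means and summed TPM of lists, lists without each member in turn, and agreement without the gene of the largest ratio. Chosen after seeing the data were scaling by the CDS share of mitochondrial reads, weighting footprints by their excess in frame 0 and the subsets of the periodicity data. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.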

Results

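Ribosome footprints and total RNA were sequenced from mitochondria of the youngest leaves of Arabidopsis thaliana, ecotype Col-0, aged 9 to 10 weeks. Wild type was compared with the P2 and P3 phenotypes of a heterozygous rps10 mutant. RPS10 (AT3G22300) is a nuclear gene for protein S10 of the small subunit of the mitochondrial ribosome, and its own level was not analysed here because the gene values cover 24 genes of the mitochondrial genome. P2 and P3 are phenotypes of the same mutant and not independent mutants. Each of the 3 kinds of plants had 1 footprint library and 1 RNA library, 6 in all, and each library pooled 15 mitochondrial preparations. No comparison therefore had a replicate check, and no p-value is given. The footprint libraries held 7744978 reads in wild type, 15131283 in P2 and 11956216 in P3 after trimming and filtering, and the RNA libraries held 4304795, 8371171 and 5670742. Of these, 416254 footprint reads in wild type, 80146 in P2 and 48653 in P3 lay on mitochondrial coding sequences (CDS), against 1971931, 3126478 and 2122781 RNA reads. Reads per gene were not given, so the depth behind a single gene's value is unknown.

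The origin of the reads was compared first. Footprints on mitochondrial CDS made up 5.37% of the footprint reads in wild type (95% Wilson interval 5.36 to 5.39), 0.530% in P2 (0.526 to 0.533) and 0.407% in P3 (0.403 to 0.411), which was 10.1-fold lower in P2 and 13.2-fold lower in P3. Mitochondrial tRNA and rRNA made up 56.7% of the footprint reads in wild type, 88.7% in P2 and 86.6% in P3. Among footprint reads on the mitochondrial genome outside tRNA and rRNA, 62.6% lay on CDS in wild type (62.5 to 62.7), 17.3% in P2 (17.2 to 17.5) and 14.9% in P3 (14.7 to 15.0). The same share in the RNA libraries was 60.4%, 47.1% and 46.2%. Reads from the plastid genome, a sign of RNA from outside mitochondria, were 5.32% of the RNA reads in wild type, 1.22% in P2 and 1.21% in P3. Reads from the nuclear genome were 4.51%, 0.725% and 0.428% of the RNA reads and 14.0%, 1.90% and 1.77% of the footprint reads. These intervals cover counting error only, since sequenced fragments are copies made by amplification and preparations were pooled. Wild-type mitochondria came from about 30 g of leaves per isolation and mutant mitochondria from about 15 g, and only mutant seedlings were raised on kanamycin. The amount of leaf, the kanamycin and the genotype therefore changed together.

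RNA levels were compared to show which mitochondrial transcripts took a larger or smaller part of the messenger RNA in each mutant phenotype. The genes for ribosomal proteins and for cytochrome c maturation, the pathway that attaches heme to cytochrome c, took a larger part in both. The 5 ribosomal protein genes measured held 5.17% of the summed RNA TPM in wild type, 14.1% in P2 and 13.4% in P3, and the 4 cytochrome c maturation genes held 0.989%, 2.99% and 3.07%. Complex V, the ATP synthase, held 66.4% in wild type, 44.3% in P2 and 45.1% in P3. All 5 ribosomal genes and all 4 cytochrome c maturation genes were at least 1.5-fold higher in both phenotypes. With median-of-ratios scaling 3 ribosomal genes in P2 and 2 in P3, and 2 cytochrome c maturation genes in P2 and 3 in P3, still passed, and rpl5 turned lower in P3 (-0.0083). With CDS-share scaling 3 of the ribosomal genes and all 4 cytochrome c maturation genes passed in each phenotype. The highest log2 ratios over wild type were those of ccmB (2.20 in P2 and 2.29 in P3), rpl16 (2.06 and 2.03) and rps4 (1.67 and 1.71). The median log2 ratio of the ribosomal list was 1.49 in P2 and 1.25 in P3, with 1.49 and 1.25 for its small-subunit members and 1.45 and 1.40 for its large-subunit members, and that of cytochrome c maturation was 1.42 and 1.45. The pair of other genes, matR for a maturase and tatC for a protein of the twin-arginine transport system, was also higher, with a median of 1.22 in P2 and 1.18 in P3. All of these medians stayed above 0 under each scaling tried.

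In complex V, atp8 was lower by the 1.5-fold rule in both phenotypes (log2 ratio -1.12 in P2 and -1.23 in P3). atp9 passed it in P2 alone (-0.63, against -0.48 in P3) and atp4 in P3 alone (-0.73, against -0.49 in P2), and these differences between P2 and P3 were not tested. With median-of-ratios and with CDS-share scaling they were absent, and the same 5 of 6 genes (atp1, atp4, atp6.1, atp8 and atp9) were lower in both phenotypes. The complex V median was -0.50 in P2 and -0.53 in P3, and it stayed below 0 under each scaling. In complex I, the NADH dehydrogenase, nad3, nad6 and nad9 were 1.52-fold to 1.88-fold higher, nad4L had ratios of 0.21 and 0.17, and the median was 0.72 and 0.73. The complex I direction turned with median-of-ratios scaling, to -0.12 in P2 and -0.050 in P3. Neither cob of complex III (0.35 and 0.33) nor cox1 and cox3 of complex IV (median 0.22 and 0.22) passed the rule, and complexes III and IV were below 0 with median-of-ratios and CDS-share scaling. The whole oxidative phosphorylation (OXPHOS) list of 13 genes had a median of 0.21 in P2 and 0.17 in P3 with 3 members higher and 2 lower in each, while its summed share was 92.6% in wild type, 80.0% in P2 and 80.8% in P3. The OXPHOS median was negative with median-of-ratios scaling (-0.63 and -0.62) and when TPM were scaled by the CDS share of reads (-0.15 and -0.22). The counts then were 0 members higher and 7 lower with median-of-ratios scaling and 0 and 5 with CDS-share scaling in each phenotype, so nad3, nad6 and nad9 were called higher under neither.

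Over all 24 genes, RNA was at least 1.5-fold higher for 14 genes and lower for 2 in P2, and again for 14 and 2 in P3. The 14 higher genes were the same in both phenotypes. The median gene stood at 0.84 in P2 and 0.78 in P3. TPM sum to a fixed total, so ratios are to be read against those values. Median-of-ratios scaling, which sets the median gene to 0, gave 6 higher and 7 lower genes in each phenotype. Among 10000 random lists of the same size matched on mean TPM, the complex V median lay at percentile 0.525 in P2 and 0.475 in P3, the ribosomal median at 88.3 and 63.4, and the cytochrome c maturation median at 77.3 and 77.7. With 24 genes only a limited number of distinct matched lists exists (70 for cytochrome c maturation), so these percentiles describe these libraries and nothing more.

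Footprint levels were compared to show which mitochondrial genes held a larger or smaller part of the footprints. The frame 0 share of footprints was lower than in wild type for 24 of these 24 genes in P2 and in P3, and reads outside CDS made up 37.4% of the footprint reads on the mitochondrial genome outside tRNA and rRNA in wild type, 82.7% in P2 and 85.1% in P3, so the gene levels below were measured in libraries that also differed in these respects. Footprints on ribosomal protein genes took 1.62% of the summed footprint TPM in wild type, 21.2% in P2 and 28.2% in P3. Those on the OXPHOS genes took 97.7%, 74.2% and 65.3%, and those on complex V alone 60.6%, 31.0% and 24.2%. The largest ratios were those of matR, whose level was 220 TPM in wild type, 13538 in P2 and 21283 in P3 (log2 ratios 5.94 and 6.59), and of rpl16, at 2335, 85059 and 138128 TPM (5.19 and 5.89). Next came rps12 (4.08 and 4.17), rps4 (3.93 and 4.36), tatC (3.25 and 3.90) and rpl5 (2.96 and 3.09). The matR ratio rests on the lowest footprint TPM of any gene in wild type. The rpl16 gene overlaps rps3 in the TAIR10.1 gene table, and how the authors assigned reads in such an overlap is not given in the sources used here. Frame 0 held only 27.7% of the rpl16 footprints in wild type, 23.9% in P2 and 23.1% in P3, below the 33.3% of an even spread. Frame 1 held the largest share in each, so the rpl16 ratios carry this limit too.

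All 5 ribosomal genes were at least 1.5-fold higher in footprints in both phenotypes, with a list median of 3.93 in P2 and 4.17 in P3, although rps7 (1.08 and 1.11) turned lower than wild type with median-of-ratios or CDS-share scaling. The small-subunit median was 3.93 and 4.17 and the large-subunit median 4.07 and 4.49. All 4 cytochrome c maturation genes were higher (median 1.93 and 2.33), with ccmFN1 at 2.23 and 2.35, and this median stayed above 0 under each scaling, at 0.084 in P2 and 0.26 in P3 when scaled by the CDS share. With that scaling 0 of the 4 passed 1.5-fold, and ccmFN2 in P2 (-0.20) and ccmC in P3 (-0.023) turned lower. The 2 other genes, matR and tatC, had medians of 4.59 and 5.25. Complex V was lower, with a median of -0.99 in P2 and -1.29 in P3 and 4 of 6 members past the rule: atp4 (-1.69 and -2.32), atp9 (-1.31 and -1.96), atp1 (-1.01 and -1.27) and atp8 (-0.97 and -1.32). The copy atp6.2 went the other way (1.74 and 1.91) while atp6.1 had ratios of -0.12 and -0.35. These copies are nearly identical over much of their length, so reads could be divided between them by the authors' counting, and atp6.2 turned lower with CDS-share scaling (-0.11 and -0.16).

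In complex I, nad3 (-1.57 and -1.94) and nad4L (-0.79 and -1.04) were lower, although nad4L was not called in P2 without the most abundant gene, nad6 was higher (0.92 and 0.99) but turned lower with both of those scalings, and nad9 had ratios of -0.10 and -0.09. The complex I median was -0.45 in P2 and -0.57 in P3. In complex IV, the cytochrome c oxidase, cox1 was lower (-0.89 and -1.34) and cox3 was higher (1.52 in both), with a median of 0.32 and 0.09 that turned negative under both scalings and without cox3 itself. The cox3 gene had the highest footprint TPM in both phenotypes (189461 and 189713), and its ratio was -0.33 in P2 and -0.55 in P3 after CDS-share scaling. For cob of complex III the ratios were 0.36 and 0.26, and they were negative under both scalings. The OXPHOS median was -0.79 in P2 and -1.04 in P3, with 3 members higher and 7 lower of 13 in each. Median-of-ratios scaling gave 0 higher and 10 lower in P2 and 1 and 10 in P3, and CDS-share scaling gave 0 and 11 in each.

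Over all 24 genes, footprints were higher for 14 genes and lower for 7 in both P2 and P3, and the same 14 and the same 7 genes passed in each. The direction also went with the wild-type footprint level. Apart from nad6 and cox3, each gene called higher had at most 7876 TPM in wild type (atp6.2). Each gene called lower had at least 20459 TPM there (nad4L). The median gene stood at 1.30 in P2 and 1.32 in P3. Median-of-ratios scaling gave 8 higher and 10 lower genes in P2 and 11 higher and 10 lower in P3, and CDS-share scaling gave 6 higher and 12 lower in each. The gap between the ribosomal and OXPHOS medians does not depend on such scaling, and it was 4.71 log2 units (26.2-fold) in P2 and 5.21 (37.0-fold) in P3, against 1.28 (2.43-fold) and 1.09 (2.13-fold) for RNA. Among matched random lists the ribosomal footprint median lay at percentile 95.3 in P2 and 98.3 in P3, the OXPHOS median at 8.90 and 1.06, the complex V median at 5.52 and 11.7, and the cytochrome c maturation median at 18.1 and 47.3. The OXPHOS percentile rests on 56 distinct matched lists in P2 and 3584 in P3 and the ribosomal percentile on 1568 and 3584, so the P2 and P3 percentiles of a list are not comparable. The mean TPM used for matching includes the mutant, so genes that rose, such as rpl16, were matched with genes of higher wild-type level. The ribosomal percentile is thus partly built in and is not a comparison with genes of like wild-type level. In simulated libraries with noise set from the spread of P3 over P2, the 1.5-fold rule called 4.61 of 12 unchanged genes in P2 and 4.58 in P3 on average. With ratios centred on the median gene it called 1.83 in each, so calls depend on the scaling as well as on noise. Single genes close to 1.5-fold are uncertain. So are some further from it, since cox3, 2.87-fold higher in P2 on the TPM scale, turned lower with CDS-share scaling.

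**Figure D1:**
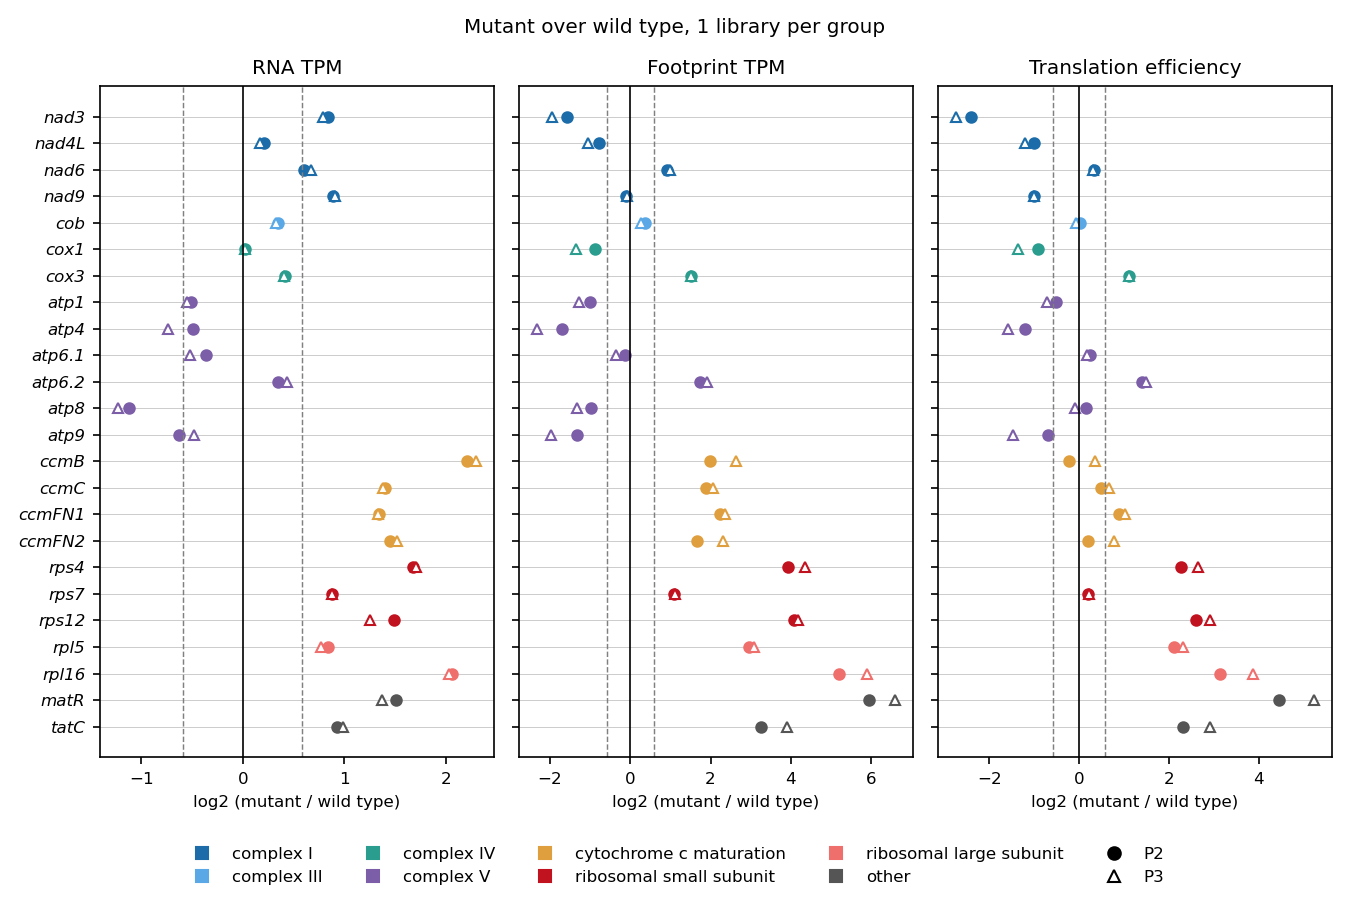
Log2 ratio of mutant over wild type (horizontal axis) for RNA TPM, footprint TPM and translation efficiency of the 24 genes (vertical axis), coloured by gene group, with filled circles for P2 and open triangles for P3 and dashed lines at 1.5-fold. There was 1 library per group, so no error bars are drawn. On this TPM scale the ribosomal protein genes had a median footprint ratio of 3.93 in P2 and 4.17 in P3 and the OXPHOS genes -0.79 and -1.04. Of the genes past 1.5-fold in footprints, rps7, nad6, cox3 and atp6.2 fell below wild type under CDS-share scaling in both phenotypes, ccmFN2 in P2 and ccmC in P3.

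Translation efficiency, footprint TPM over RNA TPM of the same gene, was compared to set footprint differences against RNA differences, and the frame 0 and outside-CDS differences of the footprint libraries apply to it as well. It was higher in both phenotypes for 4 of the 5 ribosomal protein genes. These were rpl16 (log2 ratio 3.13 in P2 and 3.86 in P3), rps12 (2.59 and 2.91), rps4 (2.26 and 2.65) and rpl5 (2.11 and 2.32), while rps7 had ratios of 0.20 and 0.23 and was called lower in both with CDS-share scaling and higher in both without the most abundant gene. The list median was 2.26 in P2 and 2.65 in P3, with 2.26 and 2.65 for the small-subunit members and 2.62 and 3.09 for the large-subunit members. It stayed above 0 under each scaling. The efficiency of matR was 0.0330 in wild type, 0.714 in P2 and 1.23 in P3 (4.44 and 5.23), that of tatC was 0.206, 1.02 and 1.55 (2.31 and 2.91), and the median of this pair was 3.38 and 4.07.

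Efficiency was lower for nad3 (5.20 in wild type, 0.979 in P2 and 0.781 in P3, log2 ratios -2.41 and -2.74), nad4L (-0.99 and -1.21) and nad9 (-0.996 and -1.004) of complex I, for atp4 (-1.20 and -1.59) and atp9 (-0.68 and -1.48) of complex V, and for cox1 (-0.91 and -1.37). It was higher for cox3 (1.11 and 1.11), atp6.2 (1.40 and 1.48) and ccmFN1 (0.89 and 1.02), and these 3 turned lower with CDS-share scaling. The complex I median was -0.995 in P2 and -1.11 in P3, with 3 of 4 members lower, and it stayed below 0 under each scaling. Without the most abundant gene of each kind of library it was -0.56 and -0.72, and nad4L, nad9 and cox1 were no longer called in P2, which left nad3 as the 1 complex I member lower in P2, while nad6 was then called higher in both. The OXPHOS median was -0.51 and -0.72, with 6 of 13 members lower in P2 and 7 in P3 and 2 higher in each, against 2 of 11 lower in P2 and 5 in P3, and 4 and 2 higher, without the most abundant gene. Median-of-ratios scaling gave 2 higher and 7 lower in P2 and 1 and 9 in P3, and CDS-share scaling gave 0 higher and 11 lower in each. The complex V median was -0.18 and -0.41 and turned to 0.59 and 0.30 once the most abundant gene of each kind of library was left out. Cytochrome c maturation had a median of 0.35 in P2, with 1 of 4 members higher, and 0.73 in P3, with 3 higher, and turned to -1.15 and -0.96 with CDS-share scaling and, in P2, to -0.12 with median-of-ratios scaling. Its counts were then 0 higher and 4 lower in each phenotype with CDS-share scaling. With median-of-ratios scaling they were 0 higher and 1 lower (ccmB) in P2 and 0 and 0 in P3. Complex IV had a median of 0.10 in P2 and -0.13 in P3 from cox1 and cox3 moving apart, and the ratios of cob were 0.011 and -0.068.

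Over all 24 genes, efficiency was higher for 9 genes and lower for 6 in P2, and higher for 11 and lower for 7 in P3, around a median gene at 0.23 and 0.33. CDS-share scaling gave 6 higher and 16 lower genes in each phenotype, and leaving out the most abundant gene gave 14 higher and 2 lower in P2 and 13 and 5 in P3. The gap between the ribosomal and OXPHOS medians was 2.76 log2 units (6.79-fold) in P2 and 3.37 (10.3-fold) in P3. The ribosomal median lay at percentile 90.1 in P2 and 96.9 in P3 among matched random lists, the OXPHOS median at 17.9 and 4.31, and the cytochrome c maturation median at 18.4 and 23.0, with the same numbers of distinct matched lists as for footprints. The matching again used a mean that includes the mutant libraries, with the same limit.

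The P2 and P3 phenotypes were then set against each other. For RNA, none of the 24 genes differed by 1.5-fold between them, and the largest log2 ratio of P3 over P2 in size was that of atp4 (-0.24). For footprints, rpl16 (0.70), matR, tatC, ccmB and ccmFN2 (0.65 each) were higher in P3 and atp9 (-0.65) and atp4 (-0.63) were lower. The ratios of ccmB, ccmFN2 and tatC were the same to 6 significant digits, as equal read counts in P2 and P3 would give, and the reads behind them, which can be few, are unknown. None of these 7 genes reached 2-fold, and with CDS-share scaling 0 genes were higher and 4 lower. For efficiency, matR (0.79), rpl16 (0.73) and tatC (0.60) were higher in P3 and atp9 (-0.80) was lower. Weighted by the frame 0 excess, the median of matR and tatC turned to -0.12 in footprints and -0.082 in efficiency, and 2 genes were higher and 5 lower in footprints. The median of P3 over P2 in footprints was 0.14 for the ribosomal list and -0.25 for OXPHOS, and the ribosomal median turned below 0 with CDS-share scaling.

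The ratios of P2 and P3 over wild type were close across genes. Pearson r over the 24 genes was 0.994 for RNA, 0.996 for footprints and 0.991 for efficiency, and the sign was shared by 24, 24 and 21 of the 24 genes. Simulated unchanged libraries that shared the wild-type library gave r of 0.492 for each quantity and a shared sign for 66.8%, 66.7% and 66.6% of genes. These simulated values follow from giving all 3 libraries equal noise and would be about the same for any data, so they are no test. The covariance was 0.80 for RNA against a simulated 0.0048, 5.48 for footprints against 0.085, and 3.02 for efficiency against 0.080. The simulated covariance is set by the spread of P3 over P2, so closeness of P2 and P3 itself makes it small. In footprints 14 genes were higher in both phenotypes and 7 lower in both. Simulated unchanged libraries with the shared wild type gave 0.543 and 0.554 such genes, and independent lists of these sizes would share 8.17 and 2.04. The former leaves out the effects and the latter the shared library, so the excess over either is not an estimate of a shared effect. The footprint ratio was larger in size in P3 than in P2 for 22 of the 24 genes, and the RNA ratio for 12. P2 and P3 come from the same mutant and were set against the same wild-type library, which could not be split. The simulated noise of that library was taken from P3 over P2, so the simulation does not bound the deviation of the wild-type library. How much of the excess comes from the shared control is therefore unknown, and genes are not independent replicates.

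Footprint periodicity was given as the share of footprints in each of the 3 codon frames per gene or exon. Frame 0 held the largest share in 50 of 56 genes or exons in wild type, in 36 in P2 and in 34 in P3. The median frame 0 share was 57.0% in wild type, 41.0% in P2 and 41.9% in P3, where an even spread would give 33.3%. It was below the wild-type share for 54 of the 56 in P2 and 55 in P3. Among the 24 intronless genes of the TPM tables the median was 59.2%, 47.0% and 45.0%, and among the 32 exons of the intron-containing genes nad1, nad2, nad4, nad5, nad7, cox2, ccmFC, rps3 and rpl2 it was 56.4%, 35.6% and 33.3%. The frame 0 share of cox3 was 59.2% in wild type, 55.7% in P2 and 57.2% in P3, and that of atp8 was 61.1%, 55.2% and 59.3%. Frame 1 was the largest for rpl16 in all 3 libraries, at 48.1%, 61.4% and 65.3%. The leading frame likewise took a larger share in P2 and P3 for nad4_4 (frame 2, 51.8%, 66.2% and 68.8%) and nad7_1 (frame 1, 42.0%, 60.9% and 60.3%). A lower frame 0 share is therefore not always a weaker preference for 1 frame. The number of footprints behind each share was not given, so the shares carry no interval. Some can rest on few footprints, such as 50%, 50% and 0% for nad5_3 and 25%, 50% and 25% for rpl2_2 in wild type. Each such exon still counts as 1 row in the medians and leading frames above.

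**Figure D2:**
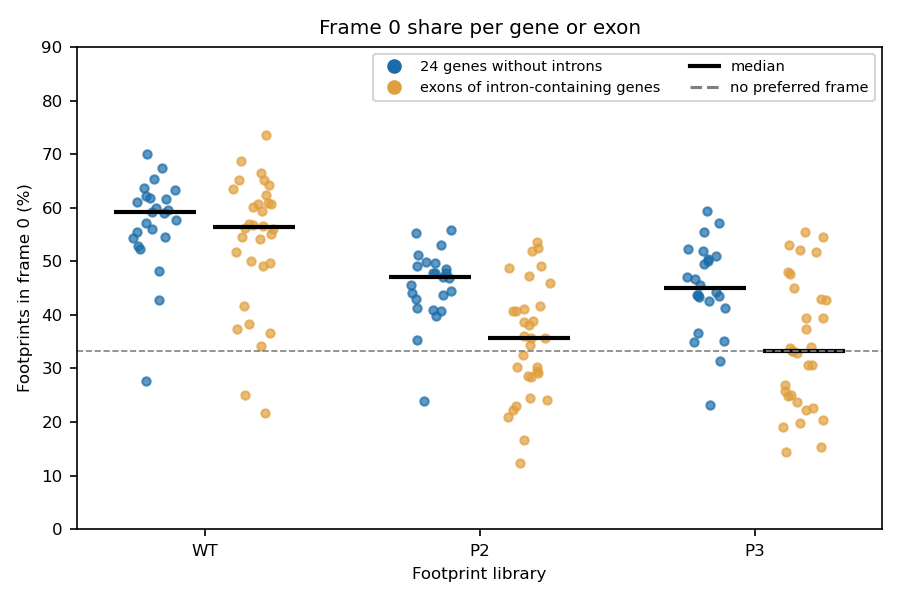
Percentage of footprints in frame 0 (vertical axis) for each gene or exon in the 3 footprint libraries (horizontal axis), with 1 point per gene or exon, blue for the 24 genes without introns and orange for the 32 exons of intron-containing genes, a bar at each median and a dashed line at 33.3%, the share with no preferred frame. The medians were 59.2% and 56.4% in wild type, 47.0% and 35.6% in P2 and 45.0% and 33.3% in P3.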

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

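The tests of explanations in this part were chosen after the results were seen. Efficiency ratios over wild type had opposite signs in P2 and P3 for 3 genes, a difference that was not tested. They were 0.154 in P2 and -0.0936 in P3 for atp8, -0.217 and 0.345 for ccmB, and 0.0111 and -0.0675 for cob. None of these passed 1.5-fold. Among 84 open reading frames outside the known genes, footprints gave a frame share for 48 in wild type, 74 in P2 and 70 in P3. The footprint reads outside CDS on the mitochondrial genome numbered 248905 in wild type, 381814 in P2 and 278786 in P3, so the mutant libraries were also deeper there. As a share of footprint reads on the mitochondrial genome they were 37.4% in wild type, 82.7% in P2 and 85.1% in P3, and the same share of RNA reads was 39.6%, 52.9% and 53.8%.

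The first pattern weighed was the larger part of footprints on ribosomal protein genes and the smaller part on OXPHOS genes. Most genes called higher also had a lower wild-type footprint TPM than those called lower, so this pattern does not tell gene group from wild-type level. RNA levels alone would leave no gap in efficiency between ribosomal and OXPHOS genes, and the gap was 2.76 log2 units in P2 and 3.37 in P3. A fall of complex V alone, spread over the other genes by the fixed TPM sum, would leave no gap between ribosomal and other OXPHOS genes, and that gap was 4.03 in P2 and 4.26 in P3. RNA fragments with the makeup of the RNA library, mixed into wild-type footprints, would keep every gene within a range. Its limits were the wild-type footprint TPM, the mutant RNA TPM and the wild-type efficiency times the mutant RNA TPM, the level that translation as in wild type would give. Of the 21 genes past 1.5-fold, 7 (atp6.2, atp9, cox3, nad4L, rpl16, rps12 and rps4) lay over 1.5-fold outside that range in both phenotypes. In P2 the distance was only 1.62-fold for atp9, 1.65-fold for rps4, 1.68-fold for rpl16 and 1.72-fold for nad4L, and its noise is unknown. How reads of atp6.2 and rpl16 were assigned is not given either, so the 7 genes are not equally secure. Because TPM sum to a fixed total, genes above their range push others down. The positions of atp9 and nad4L below it are therefore not separate from those of the genes above it. For the other 14 genes, matR among them, RNA fragments of that makeup and a difference in ribosome occupancy cannot be told apart. Their levels lay inside that range or within 1.5-fold of it in at least 1 phenotype. Fragments with another makeup, the leaf amount per isolation, the raising of mutant seedlings on kanamycin and the rps10 genotype also remain open and may act together.

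The second pattern was the lower frame 0 share in P2 and P3. Fewer footprints behind each share would scatter shares in both directions, and 54 of 56 genes or exons were lower in P2 and 55 in P3. RNA fragments without a frame would lower frame 0 most where RNA is high relative to footprints. Across 23 genes the Spearman rho between the part of the frame 0 excess that was lost and the ratio of RNA to footprint TPM was 0.349 in the phenotype with the lower value and 0.384 in the other. Such a rho across genes, which are not independent, leaves RNA fragments and a true change in the ribosomes' frame open for those 23 genes. A different nuclease digestion of the mutant lysates may also contribute and was not tested. The exons of intron-containing genes were not in this rho. Fragments without a frame could bring a share down to 33.3% and no lower. The lower quartile of frame 0 over the 32 exons was 49.5% in wild type, 28.5% in P2 and 24.6% in P3. For exons that fell below 33.3%, this argues against such fragments as the only cause, although the footprints behind each share are unknown.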

How the results depend on the processing

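Scaling by the CDS share, weighting by frame 0 and the subsets of periodicity data were chosen after seeing the data; the other settings were planned. No paired analysis was possible because each group had 1 library. Pseudocounts of 100 and 1 TPM left every count of genes as it was, a minimum mean of 1000 TPM removed 0 genes, and restricting lists to intronless members changed nothing because all 24 genes are intronless. CPM values and the most frequent read length were not run, because neither read counts per gene nor read lengths were used here. Agreement between P2 and P3 was between 0.964 and 0.996 by Spearman rho, without the gene of the largest ratio, or both. Where a scaling multiplies all genes of a library alike, its construction is the cause of each shift below; for the other settings the cause was not tested. The shifts in P2 and P3 were -0.84 and -0.78 (RNA), -1.30 and -1.32 (footprints) and -0.47 and -0.53 (efficiency) with median-of-ratios scaling, and -0.36 and -0.39, -1.85 and -2.07, and -1.49 and -1.69 with CDS-share scaling; leaving out the most abundant gene shifted them by -0.23 and -0.18, 0.20 and 0.21, and 0.43 and 0.39. Leaving out each member in turn kept the ribosomal footprint median between 3.44 and 4.00 in P2 and between 3.63 and 4.26 in P3 and the OXPHOS footprint median between -0.84 and -0.45 and between -1.15 and -0.69, while the complex V efficiency median in P2 ranged from -0.51 to 0.15. Unknown depth per gene limits every ratio.

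With median-of-ratios scaling, RNA had 6 higher and 7 lower genes in P2 and 6 and 7 in P3, footprints had 8 higher genes in P2, and efficiency had 7 higher genes in P3. RNA medians in P2 and P3 were -0.12 and -0.050 for complex I, -1.34 and -1.31 for complex V, -0.63 and -0.62 for OXPHOS, 0.59 and 0.67 for cytochrome c maturation, and 0.65 and 0.47 for ribosomal genes. Among genes past 1.5-fold on the TPM scale, RNA ratios turned for nad3 in P2 (-0.0029), nad6 (-0.24 and -0.11) and rpl5 in P3 (-0.0083). Genes that had not passed turned as well, among them nad4L and cox1, which were then called lower in both phenotypes. Footprint medians were -2.29 and -2.61 for complex V, -2.09 and -2.36 for OXPHOS, 0.63 and 1.01 for cytochrome c maturation, and 2.62 and 2.85 for ribosomal genes. Among genes past 1.5-fold on the TPM scale, footprint ratios turned for nad6 (-0.38 and -0.32) and rps7 (-0.22 and -0.21). The cob ratio, which had not passed, also turned, and cob was then called lower in both phenotypes.

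With CDS-share scaling, RNA had 8 higher and 5 lower genes in P2 and 9 and 5 in P3, footprints had 6 and 12 in each, and efficiency had 16 lower genes in P2 and 6 higher and 16 lower in P3. For P3 over P2, footprints had 0 higher and 4 lower genes and efficiency 1 and 3. Footprint medians in P2 and P3 were -2.84 and -3.37 for complex V, -2.64 and -3.12 for OXPHOS, 0.084 and 0.26 for cytochrome c maturation, and 2.08 and 2.09 for ribosomal genes. Efficiency medians were -1.67 and -2.09 for complex V, -1.999 and -2.41 for OXPHOS, -1.15 and -0.96 for cytochrome c maturation, and 0.76 and 0.96 for ribosomal genes. Among genes past 1.5-fold on the TPM scale, footprint ratios turned for atp6.2 (-0.11 and -0.16), cox3 (-0.33 and -0.55), nad6 (-0.93 and -1.08), rps7 (-0.77 and -0.97), ccmFN2 in P2 (-0.20) and ccmC in P3 (-0.023). As with median-of-ratios scaling, cob turned too and was called lower in both phenotypes. Among genes past 1.5-fold on the TPM scale, efficiency ratios turned for atp6.2 (-0.095 and -0.21), ccmFN1 (-0.60 and -0.67), cox3 (-0.38 and -0.57) and, in P3, ccmC (-1.01) and ccmFN2 (-0.90). Genes that had not passed turned as well, among them rps7 and nad6, which were then called lower in both phenotypes.

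With the 2-fold threshold, RNA had 8 higher genes and 1 lower in each phenotype, footprints had 4 lower genes in P2, efficiency had 2 lower genes in P2, and P3 over P2 had 0 higher and 0 lower in footprints and in efficiency, as the stricter limit allows. Without the most abundant gene (atp9 for RNA, cox3 for footprints), RNA had 4 lower genes in each phenotype, efficiency had 14 higher and 2 lower in P2 and 0 lower for P3 over P2, and the complex V efficiency median was 0.59 in P2 and 0.30 in P3. Weighted by the frame 0 excess, which gives no value for rpl16 and ccmFN2, P3 over P2 had 2 higher and 5 lower genes in footprints and 5 lower in efficiency, and the matR and tatC median of P3 over P2 turned to -0.12 in footprints and -0.082 in efficiency. The cytochrome c maturation efficiency median in P2 was 1.05. The gap between ribosomal and OXPHOS medians was then 3.93 in P2 and 4.24 in P3 for footprints and 3.42 in P2 for efficiency, and with list means the footprint gap was 3.75 and 4.26. Open reading frames with a value in all libraries had a median frame 0 share of 49.7% in wild type, 33.8% in P2 and 33.3% in P3, below wild type for 27 and 24 of 42.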

Other observations

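Efficiency was spread less widely over genes in P2 and P3. Its SD on the log2 scale over the 24 genes was 1.49 in wild type, 0.92 in P2 and 1.05 in P3, and the ratio of the highest to the lowest gene was 158-fold, 17.1-fold and 19.9-fold. In wild type the extremes were nad3 (5.20) and matR (0.0330), which had the lowest footprint TPM there, and in P2 and P3 they were cox3 (4.02 in P2 and 4.03 in P3) and nad4L (0.235 and 0.203). The lower frame 0 shares and larger outside-CDS shares of the mutant footprint libraries apply to this spread as well. RNA fragments among the footprints would bring efficiencies nearer to 1, as happened for nad3 and matR. Those of cox3 (1.86 in wild type) and nad4L (0.469) moved away from 1, which fragments with the makeup of the RNA library alone would not give. For the narrower spread as a whole, RNA fragments and a change in translation cannot be told apart here. Pearson r between log2 footprint and log2 RNA TPM across genes was 0.866 in wild type, 0.812 in P2 and 0.726 in P3.

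Some exons of intron-containing genes, singled out after their values were seen, had another leading frame in P2 and P3. For ccmFc_2, an exon of a cytochrome c maturation gene, frame 0 held 60.7% in wild type, 12.3% in P2 and 14.4% in P3, and frame 2 held 17.6%, 59.7% and 57.2%. For nad7_3 of complex I, frame 2 held 25.5%, 53.7% and 59.8%, and for nad4_2 frame 0 held 54.5%, 24.5% and 20.4%. The numbers of footprints behind these shares are unknown.

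The share of mitochondrial RNA reads with 1 to 5 mismatches was 8.93% in wild type, 17.2% in P2 and 6.27% in P3, so the P2 library stood apart from the others. For footprints it lay between 17.5% in P2 and 23.6% in wild type. The footprint ratio of P3 over P2 shared by ccmB, ccmFN2 and tatC was 1.57-fold. Equal read counts of each gene in both libraries would give such a shared ratio, which was not tested because reads per gene were not used here, so these 3 ratios can rest on few reads.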
